A study of Homo sapiens with 6 samples.

How the data were processed

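The measurement was RNA-seq of BAP-treated H1 cells (BMP4, A83-01 and PD173074) 72 h after transfection with VTCN1 siRNA or scrambled siRNA. Libraries were made with a stranded mRNA kit, per the labels' protocols. The submitters' processing notes name cutadapt, Bowtie, TopHat2 2.0.13, Cuffdiff 2.2.1 and HTSeq, with the genome build GRCh38. The deposited table holds values on a log2 scale, per gene symbol, with 58527 rows. How the authors went from counts to these log2 values, and whether values were adjusted for passage, is not given in the sources used here. In 22502 rows all 6 libraries are listed at 0, and whether these genes had reads is not given in the sources used here. The spread between libraries shrinks towards low levels: the median within-group SD was 0.00463 for genes with a mean of 2 or less and 0.0663 for genes above 10. Changes of low genes can therefore be understated.

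Column names gave the group, the passage, the flow cell and the lane, but no replicate number, so each library was placed in its group by the siRNA in its name and is called by its passage. The 6 columns of lane 1 were used, and 4 further columns of values per sample were not used. Passage p52 was run on another flow cell than p53 and p54. 5 rows name no gene and were left out of the tests. On the back-transformed scale they came to 6.88% (reads in no feature), 7.54% (ambiguous), 4.81% (not uniquely aligned) and 0% (not aligned, and low alignment quality) of the control libraries' totals. The depth of the libraries is unknown, so no counting interval was computed.

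The plan fixed before the data were examined was a count model, or limma on log2(value + 1) should the file hold normalized values. Because the values were already logarithms, limma was run on them as deposited, and pseudocounts of 0.25, 1 and 5 on the linear scale were tried as alternatives. A gene was tested if its value reached log2(10), or 3.32, in at least 3 libraries, which left 16230 genes. limma 3.58.1 (lmFit, and eBayes with trend and robust estimation) in R 4.3.3 compared knock-down with control, with group as the only term, and p was adjusted after Benjamini and Hochberg with a threshold of 0.05. All changes are knock-down minus control on the log2 scale, with limma's SE.

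The passage in the column names is shared by 1 control and 1 knock-down library, which also share a flow cell, so a second fit with passage as a block was made and its counts stand beside those of the fit without it. Deviations from the group means of the 2 libraries of a passage correlated at -0.872 (p52), -0.736 (p53) and -0.691 (p54) over genes. The mean square between passages was below the residual mean square in 84.1% of genes, with a median ratio of 0.152. Where passage means have been made equal, a fit without the block counts more residual degrees of freedom than the values hold. Every limma SE printed here is from the fit without the block. With the block the SE of most named genes was larger, as for B2M (0.087 against 0.057), and that of a few was smaller, as for DUSP4 (0.103 against 0.114).

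29 gene lists were written from textbook knowledge before the data were examined, holding 761 symbols, of which 760 were found in the file and 10 of these by an older name. The 28 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Genes named in the text followed a rule fixed in advance: VTCN1, the 12 largest rises and 12 largest falls among genes that passed with all knock-down libraries on 1 side of all controls (names ending in P and digits were left out), up to 4 passing members of each list by smallest adjusted p, the 2 members of highest mean in lists of the study's topic with fewer than 2 passing, and the class I genes. This gave 98 genes. NLRC5, IFI27, OAS1, IFITM3, IRF7, STAT2, CGA, CGB5, CIITA and CD74 were chosen after their values were seen. The same holds for IRF1, SOCS1, CD274, CXCL9, CXCL10 and IDO1. It also holds for the members of the MHC region listed at 0 or below the filter and the genes named only in the closing part. Coordinates are from GENCODE release 29 on GRCh38, matched by symbol.

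Alternatives were quantile normalization, upper-quartile scaling, no filter, a filter at 50, the pseudocounts, a non-robust fit, the passage block, and leaving out each library. Chosen after the data were examined were p53 and p54 alone, leaving out passage p53 or p54, and the block with an estimated correlation. The fits were tested on simulated data with the means and spreads of the 16230 genes and 200 changed genes, in 5 runs. With independent libraries, the fit without the block recovered 67.6% of changes of 0.5 and 91.4% of changes of 1 (log2), with 4.45% false calls. With passage means removed, false calls were 73.7% of all calls without the block and 1.18% with it, and the block recovered 37.8% and 79.0% of those changes. With sizes also pulled by an assumed 70% towards a common size, false calls were 94.9% and 32.2%. In the simulation camera called a list of 40 genes shifted by 0.3 in 5 of 5 runs and 0 of 100 lists with no shift. The simulated genes varied independently of one another, so this does not show how camera acts on lists of correlated genes. The correlation estimated in the data was 0.66 for the interferon-stimulated and 0.64 for the ribosomal protein list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.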

Results

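RNA was sequenced from H1 cells, a human embryonic stem cell line, that had been turned towards trophoblast, the outer lineage of the placenta, with BMP4, the TGF-β receptor inhibitor A83-01 and the FGF receptor inhibitor PD173074. On day 3 of this treatment the cells received 10 nM of an siRNA duplex against VTCN1 or of a scrambled duplex, and RNA was collected 72 h later, on day 6. VTCN1 encodes B7-H4, an immune checkpoint protein of the B7 family. Passages p52, p53 and p54 of the line each gave 1 control and 1 knock-down library, so each group held 3 libraries. Without a passage block, p-values rest on the spread among the libraries of a group and leave the pairing aside. With the block, they rest on how the knock-down minus control difference varies over the passages. The values were on a log2 scale, so the sequencing depth of each library is unknown. Of 58522 gene rows, 22502 were listed at 0 in all 6 libraries and 16230 passed the filter and were tested. The series was set up to find which genes depend on VTCN1, with trophoblast differentiation, inflammatory genes and MHC class I named in its title.

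VTCN1 was lower in every knock-down library than in every control library. Its level was 13.52 ± 0.07 in the controls and 11.68 ± 0.16 in the knock-down libraries (SD, n = 3 per group), a fall of -1.84 ± 0.08 on the log2 scale (SE), which left 28% of the control level. The knock-down library held 31.6% of the control's VTCN1 in passage p52, 29% in p53 and 24% in p54. The limma adjusted p was 5.2e-05, and 0.00175 with passage as a block. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. VTCN1 is a protein-coding gene on the minus strand of chromosome 1, from 117143587 to 117210960 (GRCh38).

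In all, 552 genes rose and 707 fell, VTCN1 included, and genes induced by interferon led the rises. Among the 12 largest rises by the rule fixed in advance were BST2, a membrane protein that tethers budding viruses (log2 change 2.13 ± 0.08, SE), OAS2, a sensor of double-stranded RNA (2.12 ± 0.07), IFI6 (1.75 ± 0.08), the antiviral GTPase MX1 (1.70 ± 0.08), OAS3 (1.65), the ubiquitin-like modifier ISG15 (1.46 ± 0.07), IFIT1 (1.41) and LGALS3BP (1.30), and also IFITM1, UBE2L6 and IFIT3. COL6A3, a chain of collagen VI, rose by 1.43 ± 0.06. Among the falls, SPP1 (-1.25) and IGFBP5 (-0.98) were left out by that rule for names ending in P and a digit. SFN, which encodes 14-3-3 sigma of epithelial cells, changed by -1.16 ± 0.06, the urokinase PLAU by -0.94 ± 0.06, the cell-cycle regulator cyclin D1 (CCND1) by -0.90 ± 0.06, PHOSPHO1 by -0.93, APOBR by -0.91, MARCH4 by -0.90, CYGB by -0.86, SERPINB7 by -0.86, the coagulation initiator F3 by -0.86, the hyaluronan receptor CD44 by -0.85 and MAP1LC3C by -0.85. Apart from SPP1 and IGFBP5, these rises and falls had limma adjusted p between 5.05e-05 and 0.000556, and at most 0.00559 with the block.

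limma called these 1259 genes at the threshold of 0.05, of which 30 rose and 3 fell by 1 or more on the log2 scale. With passage as a block, 150 rose and 116 fell, and all 266 of these were among the 1259. Leaving out any single library gave 712 to 820 calls, and ended the call of 24 of the 98 named genes, none of which passed with the block. In 84.1% of genes the mean square between passages was below the residual mean square. In simulated libraries whose passage means had been removed, 73.7% of the calls made without the block fell on unchanged genes, against 1.18% with it. Where the sizes of the differences had also been pulled by an assumed 70% towards a common size, these shares were 94.9% and 32.2%. The simulations assumed 200 changed genes of 16230, varying independently. The shares depend on that number, so they do not estimate how many of the 1259 calls are false. On the flow cell that carried p53 and p54 alone, 662 genes rose and 695 fell, and VTCN1 changed by -1.92, while the flow cell of p52 held 1 library per group and allowed no test. This fit was chosen after the data were examined, had no passage block and kept 802 of the 1259 calls. Leaving out passage p53 or passage p54 instead gave 641 and 221 calls.

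**Figure D1:**
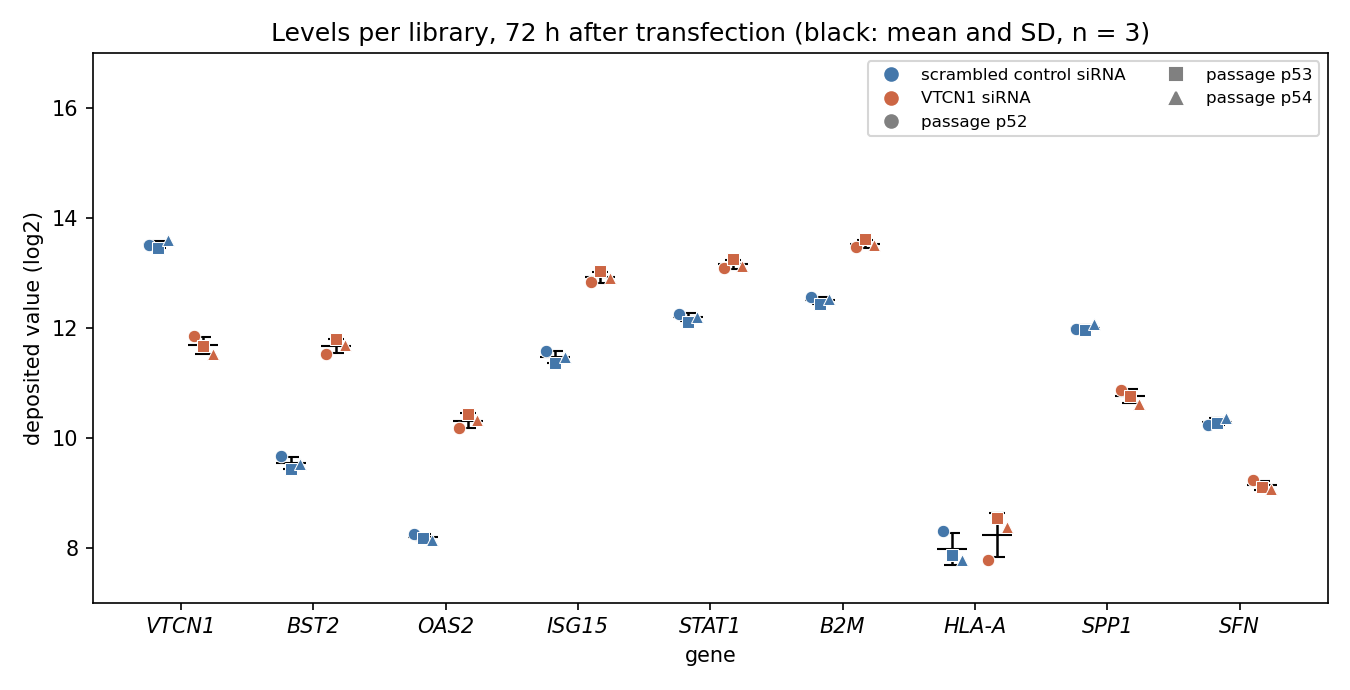
Deposited log2 values (vertical axis) of 9 genes (horizontal axis) in the 3 libraries with scrambled siRNA (blue) and the 3 with VTCN1 siRNA (orange); symbols mark the passage, and black lines the mean and SD (n = 3). VTCN1 falls from 13.52 to 11.68 and BST2 rises from 9.54 to 11.67 with no overlap, while HLA-A overlaps between the groups.

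Type I interferon-stimulated genes rose as a group. Of 46 measured members, 35 rose, none fell and 11 did not pass (38 rose when adjusted over the list alone, and 32 with passage as a block). The median change was 0.90 on the log2 scale, and the list's medians were 0.81 in p52, 1.16 in p53 and 0.93 in p54. The camera adjusted p was 8.59e-48, and adjusted p = 0.752 with an estimated correlation. Members that did not pass included IFI27, OAS1 and IFITM3, which lay lower in the knock-down library of p52 (-1.38, -0.85 and -0.74) and higher in those of p53 (1.72, 1.53 and 1.18) and p54 (1.68, 1.32 and 0.93). In the list of genes induced by interferon gamma 7 of 20 rose and none fell, counts that were the same when adjusted over the list alone, and 5 rose with the block. Examples were the guanylate-binding protein GBP1 (1.07 ± 0.06), the transcription factor STAT1 (0.97 ± 0.06), APOL6 (0.92) and APOL2 (0.54). STAT1 is also a member of the type I list. The other 13 did not pass, among them IRF1 (0.15, limma adjusted p = 0.416), SOCS1 (0.13, 0.559) and CD274 (-0.01, 0.976). CXCL9 was listed at 0, and CXCL10 and IDO1 were below the filter. Whether the rises in the gamma list are separate from those of type I genes was not tested. The camera adjusted p of this list was 0.000124, and adjusted p = 0.752 with an estimated correlation, and its medians were -0.03 in p52, 0.40 in p53 and 0.19 in p54.

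In the list of MHC class I presentation, 4 of 15 measured members rose and 1 fell (5 and 1 when adjusted over the list alone; 2 and 0 with passage as a block). B2M, the light chain shared by class I molecules, rose by 1.02 ± 0.06 (limma adjusted p = 7.58e-05), from 12.50 ± 0.06 to 13.53 ± 0.08 (SD, n = 3 per group), and the peptide-trimming enzyme ERAP1 rose by 0.49 ± 0.06 (adjusted p = 0.00229). PSME1 (0.31, adjusted p = 0.00637) and NLRC5, the transactivator of class I genes (0.14, adjusted p = 0.0256), lost the call with the block, at adjusted p = 0.124 and 0.138. The camera adjusted p of the list was 0.00247, with adjusted p = 0.752 with an estimated correlation and 0.112 without passage p53.

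The class I heavy chains gave no call over all 6 libraries except for HLA-G, which changed by -0.12 ± 0.02 (limma adjusted p = 0.0221, and 0.206 with passage as a block). HLA-A differed by 0.26 ± 0.21 (adjusted p = 0.573), HLA-B by 0.25 ± 0.11 (0.253) and HLA-C by 0.15 ± 0.09 (0.444). HLA-A was lower in the knock-down library of p52 (-0.53) and higher in those of p53 (0.68) and p54 (0.61). In p53 and p54 alone, HLA-A was higher by 0.65 (limma adjusted p = 0.000351), HLA-C by 0.32 (0.00319) and HLA-B by 0.09 (0.363). This setting was chosen after the data were examined and had no passage block. It left out p52, where HLA-C was also lower in the knock-down library (-0.19) and HLA-B was higher (0.59). Its small p-values therefore do not decide whether the heavy chains rise with the knock-down. HLA genes are similar in sequence and may share reads, so these values are uncertain.

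Many genes of the MHC region had no usable value. Of 146 protein-coding genes between ZFP57 and KIFC1 on chromosome 6 (29672392 to 33409924, GRCh38), an interval chosen after the values were seen, 96 (65.8%) were listed at 0 in all 6 libraries, against 77 of 851 (9.05%) elsewhere on the chromosome, and 14 could be tested. TAP1, PSMB8 and PSMB9 of the class I list were at 0. HLA-E (control mean 0.64, knock-down mean 0.64), HLA-F (1.40 and 1.43), TAP2 (-1.87 and -1.87) and TAPBP (0.79 and 0.80) were below the filter. RPS18, a ribosomal protein gene used by every cell, was also listed at 0. So was TNF of the inflammatory list. IER3 of that list and POU5F1 of the pluripotency list also lie in this interval and were below the filter (means of all 6 libraries 1.56 and 0.10). Of 13 genes in the class II list, 9 were listed at 0 and 2 were tested, CIITA and CD74, which lie outside this interval. For these limma gave 0 calls and 0 at an unadjusted p under 0.05. No HLA class II gene of the list could be tested.

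**Figure D2:**
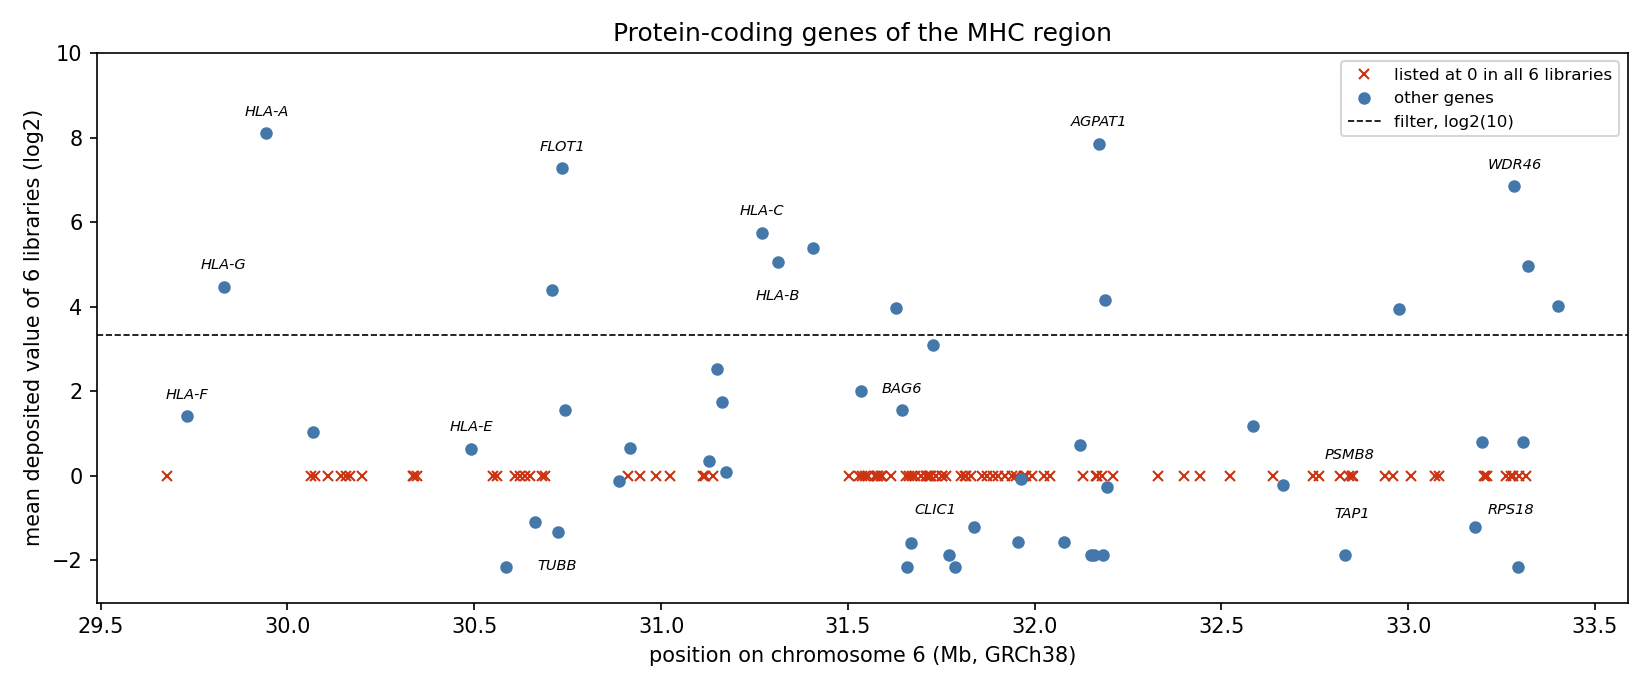
Mean deposited log2 value of the 6 libraries (vertical axis) of 146 protein-coding genes by position on chromosome 6 (horizontal axis, Mb, GRCh38); crosses are the 96 genes listed at 0 in all libraries, dots the others, and the dashed line is the filter. 14 genes could be tested, HLA-A, HLA-B, HLA-C and HLA-G among them, while TAP1, PSMB8 and RPS18 are at 0.

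Genes of the NF-κB and inflammatory list went both ways. Of 27 measured members, 2 rose and 6 fell (2 and 8 when adjusted over the list alone; 2 and 1 with passage as a block). TNF and IER3 of this list lie in the MHC region and could not be tested. The macrophage growth factor CSF1 rose by 0.58 ± 0.05 and the chemokine CCL5 by 0.28 ± 0.04. The chemokine CXCL5 changed by -0.28 ± 0.04 and the mitochondrial superoxide dismutase SOD2 by -0.34 ± 0.05, with limma adjusted p = 0.0578 and 0.116 in the blocked fit. The list fell as a group (camera adjusted p = 0.0191), with adjusted p = 0.752 with an estimated correlation, 0.104 without the control library of p52, 0.198 without the knock-down library of p52 and 0.524 in p53 and p54 alone.

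Syncytiotrophoblast genes, which mark the hormone-making fused layer of the placenta, did not move 1 way. Of 33 measured members, none rose and 2 fell, KISS1 (-0.33 ± 0.04) and the steroid dehydrogenase HSD17B1 (-0.24 ± 0.05), also when adjusted over the list alone, and only KISS1 passed with passage as a block (HSD17B1 had a limma adjusted p of 0.245 there). The list had a camera adjusted p of 0.481, against 0.00423 and 0.00767 without the control or the knock-down library of p53 and 4.36e-11 without both. CGA, the alpha subunit of chorionic gonadotropin, was lower in the knock-down library of p52 (-0.65), higher in that of p53 (1.07) and lower in that of p54 (-0.93). The signs of 22 of the 33 members followed this order, as did 11.5% of all tested genes. The list's medians were -0.29, 0.58 and -0.41. Beta subunit genes such as CGB5 (-0.84, 1.11 and -1.14) are near-identical copies, and their values are uncertain.

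In the list of extravillous trophoblast, the invasive cells of the placenta, 1 of 23 members rose and 7 fell, also when adjusted over the list alone (0 and 4 with passage as a block). The secreted matrix protein SPP1 changed by -1.25 ± 0.07, PLAC8 by -0.65 ± 0.06, the adhesion molecule MCAM by -0.64 ± 0.05 and AOC1 by -0.38 ± 0.04. The list fell (camera adjusted p = 0.00595), with adjusted p = 0.752 with an estimated correlation, 0.0611 without the control library of p52, 0.351 in p53 and p54 alone and 0.0513 without passage p54. Its medians were -0.23 in p52, 0.08 in p53 and -0.41 in p54. Of 26 cytotrophoblast members, which mark the proliferating layer, 2 rose and 2 fell (3 and 2 when adjusted over the list alone; 1 and 2 with the block), and the list had a camera adjusted p of 0.58. ID2 rose by 0.75 ± 0.05 and the Wnt receptor FZD5 by 0.34 ± 0.06 (limma adjusted p = 0.125 in the blocked fit), while the integrin chains ITGB4 and ITGA6 changed by -0.69 ± 0.05 and -0.65 ± 0.06. Of 22 genes common to trophoblast, 4 rose and 1 fell (6 and 1 when adjusted over the list alone; 2 and 0 with the block). The transcription factor HAND1 rose by 0.71 ± 0.07 and the keratin KRT7 by 0.64 ± 0.05. KRT19 (0.33) and IGF2 (0.32) had limma adjusted p = 0.168 and 0.148 in the blocked fit. This list rose (camera adjusted p = 0.0151), with adjusted p = 0.808 with an estimated correlation, 0.133 without the control library of p53, 0.161 without the knock-down library of p53 and 0.692 without both. Its medians were -0.03 in p52, 0.34 in p53 and 0.09 in p54.

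**Figure D3:**
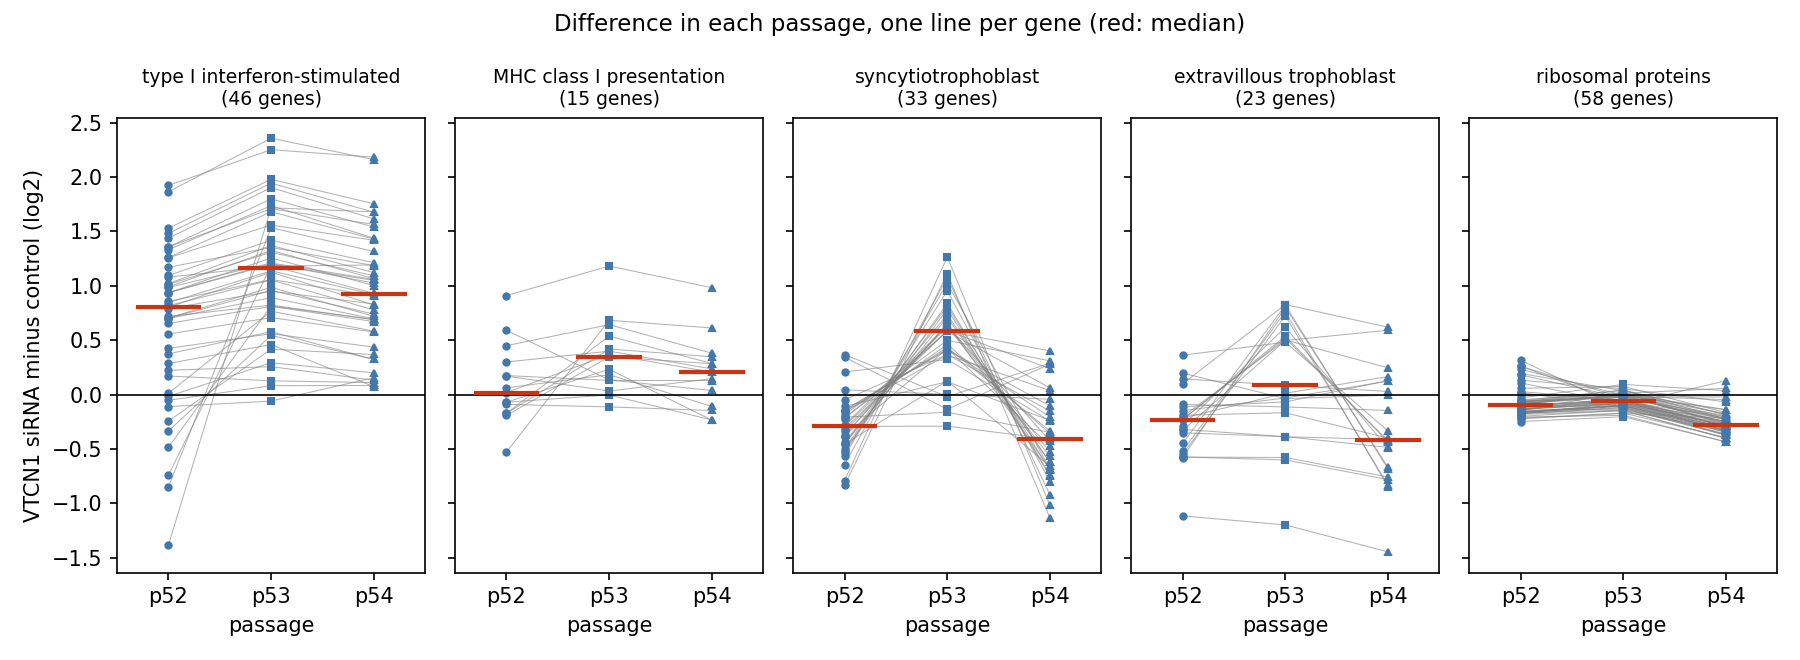
Knock-down minus control difference on the log2 scale (vertical axis) in each passage (horizontal axis) for the measured members of 5 gene lists, 1 line per gene, with the list's median in red. Medians of the interferon-stimulated list are 0.81, 1.16 and 0.93, while those of the syncytiotrophoblast list are -0.29, 0.58 and -0.41.

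Markers of other cell types gave no list call over all 6 libraries. Of 23 amnion genes, 3 rose and 4 fell (3 and 6 when adjusted over the list alone; 2 and 2 with passage as a block), among them the growth factor binding proteins IGFBP3 (0.59 ± 0.06) and IGFBP5 (-0.98 ± 0.07). The list also holds VTCN1 itself, and its camera adjusted p was 0.485. Only 8 of 22 pluripotency genes could be tested, and POU5F1 was not among them. By limma 0 of these 8 passed, also with the block, and 1 had an unadjusted p under 0.05. The camera adjusted p of the list was 0.358, against 0.0409 without the knock-down library of p53 and 0.0155 without passage p53. In the mesoderm list 1 of 16 rose and 3 fell (1 and 3 when adjusted over the list alone; 1 and 0 with the block). The receptor KDR rose by 0.63 ± 0.05, and COL1A2 (-0.34), VIM (-0.29) and LUM (-0.18) had limma adjusted p of 0.179, 0.223 and 0.488 in the blocked fit. APOB of the endoderm list (0.34) and STMN2 (-0.31) and MAP2 (-0.15) of the neuroectoderm list passed without the block and not with it (limma adjusted p = 0.161, 0.143 and 0.22). The endothelial and blood list had 5 tested genes, of which KDR rose, also with the block. Counts in the last 3 lists were the same when adjusted over the list alone. The camera adjusted p values of these 4 lists were 0.803 for mesoderm, 0.806 for endoderm, 0.467 for neuroectoderm and 0.58 for endothelial and blood genes.

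Among signalling lists, targets of TGF-β and BMP rose (camera adjusted p = 0.00228), with adjusted p = 0.752 with an estimated correlation and 0.232 without passage p53. The list's medians were -0.06 in p52, 0.38 in p53 and 0.16 in p54. Of 22 members 6 rose and 1 fell (7 and 2 when adjusted over the list alone; 4 and 0 with passage as a block). They included ID1 (0.67 ± 0.05) and ID2 (0.75 ± 0.05), inhibitors of basic helix-loop-helix factors, the inhibitory SMAD6 (0.53 ± 0.06) and the pseudoreceptor BAMBI (0.42 ± 0.05). Early genes of FGF and MAPK signalling fell (camera adjusted p = 0.000533, and adjusted p = 0.752 with an estimated correlation), with 0 of 21 rising and 4 falling (0 and 6 when adjusted over the list alone; 0 and 1 with the block). CCND1 passed both fits, while the AP-1 subunit FOSL1 (-0.33) and the MAPK phosphatases DUSP6 (-0.19) and DUSP4 (-0.52) had limma adjusted p of 0.0969, 0.253 and 0.0754 in the blocked fit. In p53 and p54 alone the list had a camera adjusted p of 0.192. CCND1 was also the single call in the list of 14 Wnt targets, with and without the block (2 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.58).

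The proliferation list fell (camera adjusted p = 0.00228, and adjusted p = 0.808 with an estimated correlation), with 4 of 40 falling (6 when adjusted over the list alone), 0 with passage as a block, where 6 had an unadjusted p under 0.05, and a camera adjusted p of 0.0765 without the control library of p54, 0.122 without passage p53 and 0.528 without passage p54. The list's medians were 0.26 in p52, -0.16 in p53 and -0.29 in p54. The replication helicase gene MCM4 changed by -0.32 and UBE2C by -0.32, with limma adjusted p = 0.113 and 0.11 in the blocked fit. Ribosomal protein genes fell (camera adjusted p = 3.1e-12, and adjusted p = 0.752 with an estimated correlation), with 7 of 58 falling (22 when adjusted over the list alone), 0 with the block, where 10 had an unadjusted p under 0.05, and a median of -0.13. RPL5 (-0.30) had a limma adjusted p of 0.0166, and 0.223 in the blocked fit. Of 13 mitochondrially encoded genes 2 rose (3 when adjusted over the list alone; 0 with the block, where 2 had an unadjusted p under 0.05), MT-ND1 (0.31) and MT-CYB (0.28), and the list's camera adjusted p was 0.00798, with adjusted p = 0.806 with an estimated correlation and 0.0525 without the control library of p52, 0.195 in p53 and p54 alone and 0.0568 without passage p53. Its medians were 0.20 in p52, 0.10 in p53 and -0.02 in p54. The matrix and adhesion list held 5 rises and 3 falls among 36 members (5 and 5 when adjusted over the list alone; 1 and 2 with the block). COL6A3 of this list rose and the basement membrane collagens COL4A1 (-0.55 ± 0.06) and COL4A5 (-0.46 ± 0.05) fell, and the list had a camera adjusted p of 0.768.

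The remaining lists had no call by camera over all 6 libraries. The adjusted p was 0.909 for the B7 family, in which BTN3A1 rose by 0.40 ± 0.04, 0.434 for p53 and apoptosis genes and also for hypoxia genes, 0.485 for the unfolded protein response, 0.358 for cholesterol synthesis, 0.467 for RNA interference genes and 0.127 for nuclear genes of oxidative phosphorylation, which fell with quantile normalization (0.0371), without the control (0.0413) or the knock-down library (0.0327) of p52 and in p53 and p54 alone (0.00992). Cholesterol synthesis genes fell in p53 and p54 alone (0.0206), and p53 and apoptosis genes fell without passage p54 (0.00863). Both settings were chosen after the data were examined and used the preset correlation. An estimated correlation, run only over all 6 libraries, gave these 2 lists camera adjusted p = 0.88 and 0.808. Of 11 B7 genes 2 rose and 2 fell (3 and 3 when adjusted over the list alone; 1 and 1 with passage as a block). The target VTCN1 is in this list and its camera test. It is 1 of the falls and the only fall with the block, where VSIR (-0.31) had a limma adjusted p of 0.185. Of 25 p53 genes 1 rose and 5 fell (1 and 5; 1 and 1). Of 27 hypoxia genes 2 rose and 1 fell (4 and 2; 0 and 0, where 6 had an unadjusted p under 0.05), and of 25 unfolded protein response genes 1 rose and 3 fell (1 and 3; 1 and 0). In the list of cholesterol synthesis 1 of 25 rose, also with the block. In that of RNA interference 1 of 13 rose, and in that of oxidative phosphorylation 1 of 37 fell, and both calls were lost with the block, where 1 gene of each list had an unadjusted p under 0.05. In these 3 lists the counts were the same when adjusted over the list alone. Single members passed in these lists, such as ZMAT3 (0.63 ± 0.05) and CCNG1 (-0.47 ± 0.05) among p53 targets, PSAT1 (0.57 ± 0.07) in the unfolded protein response and the sterol desaturase SC5D (0.75 ± 0.05) in cholesterol synthesis. Median, mean and test differed in sign for the B7 family, amnion, mesoderm, endothelial and blood, p53 and Wnt lists. None of the 11 lists called with the preset correlation kept its call with an estimated correlation, where 1 list had an unadjusted p under 0.05.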

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

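All tests weighed here were chosen after the results were seen, except for the splits for gene lists. Reads assigned to no annotated feature, which entered no comparison, were higher in every knock-down library (21.10 ± 0.06, SD, n = 3) than in every control library (20.86 ± 0.06, n = 3), a difference of 0.24 on the log2 scale with an exact two-sided permutation p of 0.1, the smallest possible. It was seen because the knock-down libraries lay above the highest control.

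The first pattern is that large knock-down minus control differences that changed sign between passages were similar in size. In 118 genes of mixed sign with a mean absolute difference of at least 0.5, the median coefficient of variation of the 3 absolute differences was 0.262, while 100 simulations with free sizes gave 0.514 to 0.651. The simulated genes varied independently, while genes such as CGA and CGB5 shared the order of their signs, so the simulated range can be too narrow. An exchange of the 2 libraries of a passage is argued against by VTCN1, whose smallest fall over the 3 passages was -1.66, and by interferon-list medians above 0 in all 3. An adjustment of the values for passage in mean and in scale before deposit stays open: the 0.262 is the observation that prompted it, and the median ratio of 0.152 between passage and residual mean squares bears on the means alone. Different syncytial differentiation between wells also stays open, as its bearing on the sizes was not tested: 22 of 33 syncytiotrophoblast genes shared the order of CGA, against a 95th percentile of 7 in 10000 random lists of like level. These lists were drawn gene by gene, so a list of genes that vary together could exceed 7 whatever the cause.

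The second pattern is the rise of interferon-stimulated genes. Blood cells are argued against, since the highest knock-down mean of 12 blood markers was 3.1 (TYROBP) and none reached the filter, while BST2 stood at 11.67. An offset common to all genes in the deposited values is argued against, since the median change over all tested genes was 0.00985. Whether RNA composition or amount differed before the authors' processing cannot be read from this, as that processing may itself have levelled the groups. The list's median change stayed at 0.89 with quantile normalization and 0.90 with upper-quartile scaling. Both settings align groups that were already nearly level, so they add little to this. A response to the VTCN1 siRNA duplex as such cannot be told apart from a response to the fall of VTCN1 RNA. The design held 1 group with a VTCN1 siRNA and no second duplex or rescue, and these data hold no protein levels. Both responses stay open.

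The third pattern is the MHC region, where 65.8% of protein-coding genes were listed at 0. Lack of transcription as the whole cause is argued against by RPS18, listed at 0 while the other ribosomal protein genes had a median level of 14.2. A candidate explanation is that reads in duplicated reference sequence (alternate haplotypes) were left out of the counts. In another region with a long alternate haplotype, on chromosome 17 from ARHGAP27 (45393902) to NSF (46757464), 4 of 13 genes were at 0. Elsewhere on the chromosome 110 of 1117 were at 0 (two-sided Fisher's exact p = 0.0343). The 4 were CRHR1, LINC02210-CRHR1, which overlaps it, SPPL2C and STH. KANSL1 (8.69), NSF (9.99), ARHGAP27 (6.76) and PLEKHM1 (6.74) there were well above the filter, so the test does not decide. The design holds no group that bears on this pattern.

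With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1259 genes, which 1 of the 10 reached, and the highest other gave 486. That other split exchanged the libraries of p52, and the remaining ones that part all 3 passages gave 243 and 1. With passage as a block these 4 splits gave 266 genes (real), 10, 0 and 0 by limma, with 1844, 1169, 887 and 560 genes at an unadjusted p under 0.05. The 6 splits that part a single passage gave 0 genes, with 43 to 233 at an unadjusted p under 0.05. The real split gave 11 list calls, which 3 of the 10 splits reached, and the highest other was also 11. The splits that part a single passage gave 6 to 11 list calls.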

How the results depend on the processing

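VTCN1 kept its fall and its call under all settings run, from -1.72 to -1.92, and no named gene or list changed direction with a call. Quantile normalization, upper-quartile scaling, the stricter filter, the pseudocounts and the non-robust fit kept the calls of all named genes tested there. The list tests, which were not run with the non-robust fit, changed under these settings only for nuclear oxidative phosphorylation, called with quantile normalization (0.0371). With passage as a block, 150 genes rose and 116 fell (552 and 707 without it), and 40 of 98 named genes lost the call, 0 gained it; at the preset correlation the same 11 of 28 lists were called with and without the block. Without a filter, 370 rose and 439 fell, and 18 named genes lost the call, HLA-G (0.0513) among them and none that passed with the block. In p53 and p54 alone, 662 rose and 695 fell, 18 named genes lost the call, HLA-A and HLA-C gained it, and camera gave adjusted p = 0.524 for inflammatory, 0.351 for extravillous and also for syncytiotrophoblast, 6.32e-06 for MHC class I and 0.00158 for common trophoblast genes. The setting of p53 and p54 alone was chosen after the data were examined. It left out p52, where HLA-A and HLA-C were lower in the knock-down library, so their gained calls do not decide on a rise. Leaving out a library, passage p53 or passage p54 gave 110 to 373 rises and 111 to 469 falls. The lowest counts were without passage p54. Adjusted p of lists in these settings ranged from 7.22e-05 to 0.112 (MHC class I), 0.000655 to 0.198 (inflammatory), 3.98e-06 to 0.0611 (extravillous), 0.00252 to 0.692 (trophoblast in common) and 4.36e-11 to 0.991 (syncytiotrophoblast, called only where a library of p53 was left out).

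With an estimated correlation 0 lists were called: adjusted p = 0.752 for interferon-stimulated, MHC class I, inflammatory and extravillous genes and 0.808 for genes common to trophoblast, and 0 lists at 0.868 for these 5 with the block as well. fry called 2 lists, the type I and gamma interferon lists (0.00294 and 0.0327), with 0.056 for MHC class I, 0.191 for inflammatory, 0.0816 for extravillous and 0.12 for common trophoblast genes. The estimated correlations were 0.66 (interferon-stimulated), 0.22 (MHC class I), 0.10 (inflammatory), 0.20 (extravillous) and 0.35 (common trophoblast), where the preset was 0.01. The calls at the preset thus rest on a correlation far below the estimates. The cause of the other changes was not tested. DESeq2 and limma-voom were not run because the values are not counts, and the unknown depth limits what low genes can show.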

Other observations

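Some non-coding RNAs were higher in the knock-down libraries. The nuclear RNA MALAT1 rose by 0.96 ± 0.06, the small nuclear RNA RN7SK by 1.06 ± 0.06 and the mitochondrial ribosomal RNA MT-RNR1 by 0.78 ± 0.06 (SE; limma adjusted p = 0.000164, 6.74e-05 and 0.000236, and 0.00723, 0.00175 and 0.0111 with passage as a block). The histone genes HIST1H2BD and HIST1H2AC both rose by 0.44 (0.000658 and 0.00228, and 0.0257 and 0.0475 with the block). These genes were chosen after their values were seen, and they were higher in the knock-down library of each of the 3 passages, as were the reads in no feature. Whether they share a cause with the changes of the ribosomal protein and mitochondrial lists was not tested.

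The interferon genes IFNB1 and IFNL1 lay below the filter of 3.32. Mean levels in control and knock-down libraries were 2.36 and 2.43 for IFNB1 and 2.64 and 2.68 for IFNL1. IFNA1 and IFNG were listed at 0, as was RPS18, so their levels are not known. Among genes that carry interferon signals, IRF7 rose by 0.76 (limma adjusted p = 0.000176, and 0.00723 with passage as a block), and STAT2 differed by -0.01 (0.974).

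Over all tested genes, 30.6% had the same sign of difference in all 3 passages, where chance gives 25%.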
